A study of Mus musculus with 8 samples.

How the data were processed

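Total RNA from flow-sorted mouse small intestinal epithelial cells was sequenced after preparation with the TruSeq RNA kit, per the labels' protocols. The 8 libraries comprise 4 of the CD24Mid fraction and 4 of the CD24Neg fraction, grouped by their sample titles, and the series text describes 4 biological replicates per cell type. Nothing in the sources used here ties a CD24Mid library to a CD24Neg library.

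The signal values that the authors deposited are gene-level expression estimates, 1 value for each of 23318 Ensembl genes per library, and per the file headers they are values per gene. The submitters' processing notes name Bowtie 0.12.8 and the genome build NCBIM37. The estimation tool's version, the annotation release and the tool behind the size factors are not given in the sources used here. The values carry decimals and are already scaled: the median ratio of a library to the geometric mean over libraries was 1.0104 in all libraries except CD24Neg library 6, where it was 1.0102. The low values of each library sat on a ladder of even steps, which was read as the value of 1 read over the lowest 8 steps. That value was 0.591 to 0.702 in CD24Mid and 1.08 to 1.79 in CD24Neg, and dividing a library's total by it gave the depth. The estimate assumes that 1 step is 1 read. CD24Neg libraries were therefore less precise at low values. They also listed more genes at 0, 4504 to 5085 against 3011 to 3258 in CD24Mid. Total depth alone does not set this count, since CD24Neg library 6 had the most estimated reads, 20.5 M, and listed 4504. Its reads outside mitochondrially encoded genes were 14.6 M, below the 15.8 to 17.8 M of the CD24Mid libraries. By fraction these reads were 10.1 M ± 3.01 in CD24Neg and 16.7 M ± 1.02 in CD24Mid (exact two-sided permutation p = 0.0286). A lower nuclear depth can therefore contribute to the zeros, and thinning to the lowest depth equalised total reads only. Whole reads could not be restored for nearly all genes, so no count model was applied.

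The design fixed before the data were examined foresaw counts or log-scale values. Since the unit was signal, its branch for values without counts was used. Genes with a value of at least 10 in at least 4 libraries were kept, values were centred on the median ratio, and log2(value + 0.5) was fitted in limma 3.58.1 (R 4.3.3) with lmFit and with eBayes using a trend and robust variance, without covariates and with 6 residual degrees of freedom. All adjusted p-values of single genes are from limma with Benjamini-Hochberg adjustment over the tested genes, with a threshold of 0.05. A fold change on this scale understates the change of low genes. Shares per library were compared with exact two-sided permutation tests in scipy 1.17.1.

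The 32 gene lists were also fixed before the data were examined, and 30 had at least 5 tested members. They were tested with limma's camera at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the lists. The named genes followed a rule with 3 parts: 10 genes whatever their result (Cd24a, Ptprc, Fut2, Tet1, Tet2, Tet3, Dnmt1, Dnmt3a, Dnmt3b and Uhrf1), the 6 largest positive and 6 largest negative changes among called genes without overlap of the groups, with a known symbol and within the top 40 percent of mean expression, and up to 4 members of each list by adjusted p plus a member in a direction that these miss. Genes outside this rule are named as chosen after their values were seen. Some list members are not reported here by name. They remain in the gene and list counts and are left out of the counts of named genes under the alternatives.

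The fit was tested on simulated data with changes planted in the comparison of CD24Neg against CD24Mid. Among 12703 simulated genes it recovered 25 of 50 genes changed 1.5-fold, 46 of 50 changed 2-fold and 50 of 50 at each of 4-fold and 8-fold, and it called 8 of 12503 unchanged genes. No list out of 50 random ones was called. The simulation had few changed genes, the same dispersion (0.0196) for every gene and genes drawn independently of each other. The real libraries differ in this, so these rates of false calls need not hold for them, least of all for the lists.

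The alternatives set beforehand were quantile normalization, no centring, no filter on low values, another filter (log2 value above 0 in every library of 1 group, which kept 15373 genes), limma without trend, thinning to the lowest depth, scaling to totals without the 20 most abundant genes, a test against a fold change of 1.5, pseudocounts of 0.1 and 1, leaving out each library in turn, camera with an estimated correlation and fry. Chosen after seeing the data were limma's voom weights on reads estimated from the steps, leaving out CD24Neg libraries 2 and 8, blocking on adjacent title numbers, and leaving out the mitochondrially encoded genes.

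Symbols were taken by Ensembl identifier from the GENCODE M21 annotation, which matched 21223 of 23318 identifiers and left 2095 without a symbol. That annotation is on another genome build than the one in the submitters' notes, so no coordinates are given. The share of exonic bases that Sco2 has in common with a neighbouring gene was computed within that annotation. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.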

Results

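RNA was sequenced from mouse small intestinal epithelial cells that had been sorted on CD24, a cell surface glycoprotein, after cells positive for the leukocyte antigen CD45 and cells bound by the fucose-binding lectin of Ulex europaeus had been depleted. The series title places the work in a study of 5-hydroxymethylcytosine and gene activity during intestinal differentiation, and the sorted fractions are compared here for their gene activity. There were 4 libraries of CD24Mid cells, with title numbers 1, 3, 5 and 7, and 4 libraries of CD24Neg cells, with title numbers 2, 4, 6 and 8, which the series design describes as biological replicates. The deposited values are normalised expression values per Ensembl gene, with 23318 genes in every library. The steps between the lowest values gave estimated depths of 17.3, 17.5, 18.9 and 19.4 M reads in the CD24Mid libraries and of 12.5, 12.4, 20.5 and 14.2 M reads in the CD24Neg libraries, if 1 step is 1 read. Values are given below as mean ± SD in these normalised units with n = 4 libraries per fraction, and fold changes are on the scale of log2(value + 0.5), CD24Neg minus CD24Mid.

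The first comparison asked whether the transcript of the sorting marker followed the labels. Cd24a (ENSMUSG00000047139), which encodes CD24, had a value of 2820 ± 622 in CD24Mid and 414 ± 122 in CD24Neg, a 6.91-fold difference (log2 fold change -2.79, SE 0.22, limma adjusted p = 2.35e-06). Its value lay between 2246 and 3693 in the CD24Mid libraries and between 287.0 and 563 in the CD24Neg libraries, so all 4 CD24Neg libraries lay below all 4 CD24Mid libraries. Ptprc, the gene for the depleted antigen CD45, had values of 78.5 ± 42.0 in CD24Mid and 259 ± 226 in CD24Neg, a difference that did not pass (adjusted p = 0.135). The CD24Neg spread ran from 39.96 in library 4 to 551 in library 8. Ptprc passed the threshold without library 4 (log2 fold change 2.01, adjusted p = 0.00937). It also passed in a fit blocked on adjacent title numbers, which the labels do not state to be pairs and which was chosen after the data were seen (log2 fold change 1.31, adjusted p = 0.006, range of adjusted p over 22 alternatives 0.006 to 0.926). Fut2, a fucosyltransferase of the intestinal epithelium, was too low to be tested, with values of 6.89 to 13.1 in CD24Mid and 0.687 to 6.11 in CD24Neg.

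**Figure D1:**
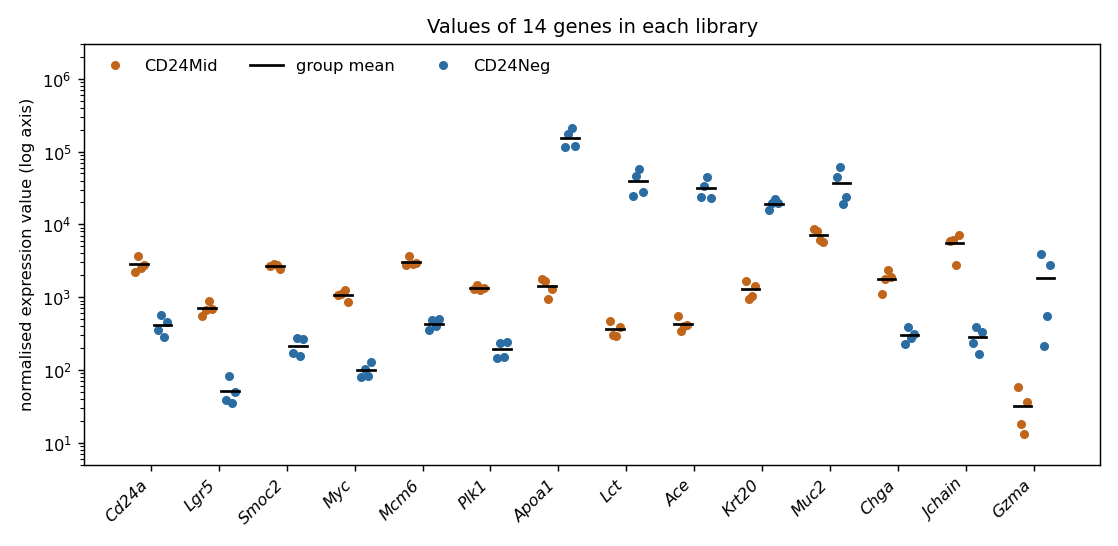
Normalised expression values (log axis) of 14 genes in the 4 CD24Mid and 4 CD24Neg libraries, with 1 point per library and a black line at each group mean. Cd24a and the stem cell and proliferation genes Lgr5, Smoc2, Myc, Mcm6 and Plk1 are lower in every CD24Neg library, Apoa1, Lct, Ace, Krt20 and Muc2 are higher in every CD24Neg library, and the Gzma values of the CD24Neg libraries spread from 212 to 3889.

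The fractions differed in most of the genes that could be tested. Of 12906 genes with a value of at least 10 in at least 4 libraries, 8809 (68.3%) passed an adjusted p of 0.05 in limma, 4386 of them higher and 4423 lower in CD24Neg. Among these, 2340 were more than 2-fold higher and 2563 more than 2-fold lower, and 407 and 328 differed by more than 10-fold. The ranges of the 2 fractions did not overlap in 8238 of the tested genes (63.8%), where chance gives 2.86% for 4 libraries against 4. The split between directions depended on the scaling. With libraries scaled to their totals without the 20 most abundant genes, 2831 genes were higher and 6534 lower, so that 30.2% of calls were higher in place of 49.8%. The median log2 fold change of all genes moved from -0.02 to -0.45. Testing against a fold change of 1.5 left 2360 higher and 2430 lower.

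Gene lists fixed before the data were examined were tested with camera, which sets each list against all other tested genes. With its preset correlation of 0.01 between genes, 12 of 30 testable lists were higher and 9 were lower in CD24Neg. None of these 21 calls held when the correlation was estimated from the libraries. There, 1 list, ribosome biogenesis, had an unadjusted p under 0.05 (0.0278). The rotation test fry called 15 lists higher and 10 lower. It takes each list on its own, and 68.3% of all tested genes were called. Its calls therefore do not set a list apart from the other genes. Counts of list members adjusted over the list alone equalled those over all genes tested except in the 6 lists where both are given.

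Markers of intestinal stem cells were lower in CD24Neg throughout. All 20 tested markers were lower, with a median log2 fold change of -3.08 (camera adjusted p = 1.11e-09, adjusted p = 0.238 with an estimated correlation). Smoc2 fell from 2689 ± 186 in CD24Mid to 217 ± 60.0 in CD24Neg, a 12.7-fold difference, Cdca7 from 2383 ± 265 to 290 ± 40.3 and Lrig1, a negative regulator of ErbB receptors, from 2445 ± 158 to 552 ± 66.2. Ephb2, a receptor tyrosine kinase that positions cells along the crypt axis, was 5.44-fold lower (2083 ± 96.3 against 388 ± 71.8). Of 17 tested Wnt target genes, 9 of which are also in the stem cell list, 15 were lower and 2 higher (median log2 fold change -3.06, camera adjusted p = 2.02e-05, adjusted p = 0.238 with an estimated correlation). Lgr5, the R-spondin receptor that marks crypt base stem cells, was 14.0-fold lower (700 ± 133 against 51.7 ± 21.6), Cd44 was 15.2-fold lower and Myc 10.9-fold lower (1074 ± 165 against 99.1 ± 22.5). The 2 Wnt targets that went the other way were Sp5, a transcription factor, at 114 ± 13.4 in CD24Mid and 299 ± 58.7 in CD24Neg, and Notum, an extracellular Wnt antagonist named after its values were seen, at 0.917 and 23.9.

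Genes of DNA replication, mitosis and ribosome production were lower in CD24Neg almost without exception. Of 37 replication genes 36 were lower (median log2 fold change -2.67, camera adjusted p = 4.75e-13, adjusted p = 0.238 with an estimated correlation). The remaining gene was not called. The helicase subunit genes Mcm6 (3052 ± 417 against 435 ± 65.9) and Mcm7 (2381 ± 232 against 339 ± 65.4) were each about 7-fold lower, and Rrm1, a ribonucleotide reductase subunit, was 8.34-fold lower. All 30 mitosis genes were lower, with a median log2 fold change of -3.03 (camera adjusted p = 2.11e-11, adjusted p = 0.333 with an estimated correlation). The mitotic kinases Plk1 (1334 ± 82.6 against 194 ± 52.6) and Aurka (814 ± 40.9 against 114 ± 29.1) and the cyclin Ccnb1 (1419 ± 115 against 206 ± 53.7) stood for these. All 26 ribosome biogenesis genes were lower, with a median of -2.07 (camera adjusted p = 2.11e-11, adjusted p = 0.238 with an estimated correlation). Among them were Npm1 (8635 ± 725 against 2138 ± 208) and Nop56 (2354 ± 87.3 against 386 ± 82.9). The CD24Mid libraries in which the stem cell and proliferation genes were higher also held more plasma cell transcripts, 0.105% ± 0.0361 of nuclear-gene values against 0.0038% ± 0.0013.

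The genes of the absorptive surface were higher in CD24Neg. All 16 brush border digestive enzymes were higher, with a median log2 fold change of 4.36 (camera adjusted p = 3.65e-09, adjusted p = 0.238 with an estimated correlation). Lct, which encodes lactase, rose from 367 ± 84.4 in CD24Mid to 39250 ± 15540 in CD24Neg, Ace, which encodes angiotensin-converting enzyme, from 429 ± 92.1 to 31360 ± 10520. Ggt1, a gamma-glutamyltransferase, rose from 86.9 ± 24.7 to 11890 ± 1444, a 140.5-fold difference. All 13 genes of microvillus structure were higher (median 2.62, camera adjusted p = 5.61e-08, adjusted p = 0.238 with an estimated correlation). The actin-bundling gene Espn was at 60.2 ± 16.5 against 2486 ± 420 and the keratin gene Krt20 at 1277 ± 352 against 19260 ± 2653. Of 11 villus tip genes, 8 of which also stand in other lists, 10 were higher (median 2.98, camera adjusted p = 0.000311, adjusted p = 0.238 with an estimated correlation). Apoc3 was 63.8-fold higher and the cell cycle inhibitor Cdkn1a 4.73-fold higher. Egfr, the epidermal growth factor receptor gene, was 2.08-fold lower (676 ± 142 against 321 ± 42.1). The CD24Neg libraries in which these genes were higher also had the larger share of mitochondrially encoded transcripts, 32.6% ± 4.63 against 8.58% ± 0.518.

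Lipid handling and nutrient uptake genes followed the same direction. Of 21 genes of lipid absorption and lipoproteins 20 were higher in CD24Neg (median log2 fold change 3.67, camera adjusted p = 4.09e-10, adjusted p = 0.238 with an estimated correlation). The apolipoprotein genes Apoa1 (1425 ± 386 against 155100 ± 46660) and Apoa4 (1182 ± 356 against 119400 ± 51410) were 108-fold and 97.2-fold higher, and Fabp2, an intestinal fatty acid binding protein gene, was 22.0-fold higher. Scarb1, named after its values were seen, was the member that did not pass (95.8 against 157, adjusted p = 0.105). Of 25 transporters 23 were higher and 1 was lower (adjusted over the list alone, 23 and 2, with a median of 3.09, camera adjusted p = 7.82e-09 and adjusted p = 0.262 with an estimated correlation). The peptide transporter Slc15a1 was at 71.4 ± 13.1 against 5608 ± 2574, the neutral amino acid transporter Slc6a19 at 161 ± 62.7 against 8732 ± 2038 and the nucleoside transporter Slc28a1 at 18.5 ± 5.26 against 1825 ± 447. The monocarboxylate transporter Slc16a1 was lower in CD24Neg (2922 ± 154 against 1920 ± 177). All 24 genes of xenobiotic metabolism were higher (median 3.4, camera adjusted p = 4.09e-10, adjusted p = 0.238 with an estimated correlation). Cyp3a25 was 77.2-fold and Cyp2d26 33.8-fold higher. All 7 genes of ileal bile acid handling were higher as well (median 4.17, camera adjusted p = 0.000477, adjusted p = 0.238 with an estimated correlation). The bile salt exporter subunits Slc51a and Slc51b were 8.41-fold and 18.1-fold higher. Fgf15, a hormone gene induced by bile acids, had 10.4 ± 3.94 against 376 ± 133. The uptake transporter Slc10a2 had values of 0.943 to 2.54 in CD24Mid, within a few reads of 0, and of 52.6 to 195 in CD24Neg.

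**Figure D2:**
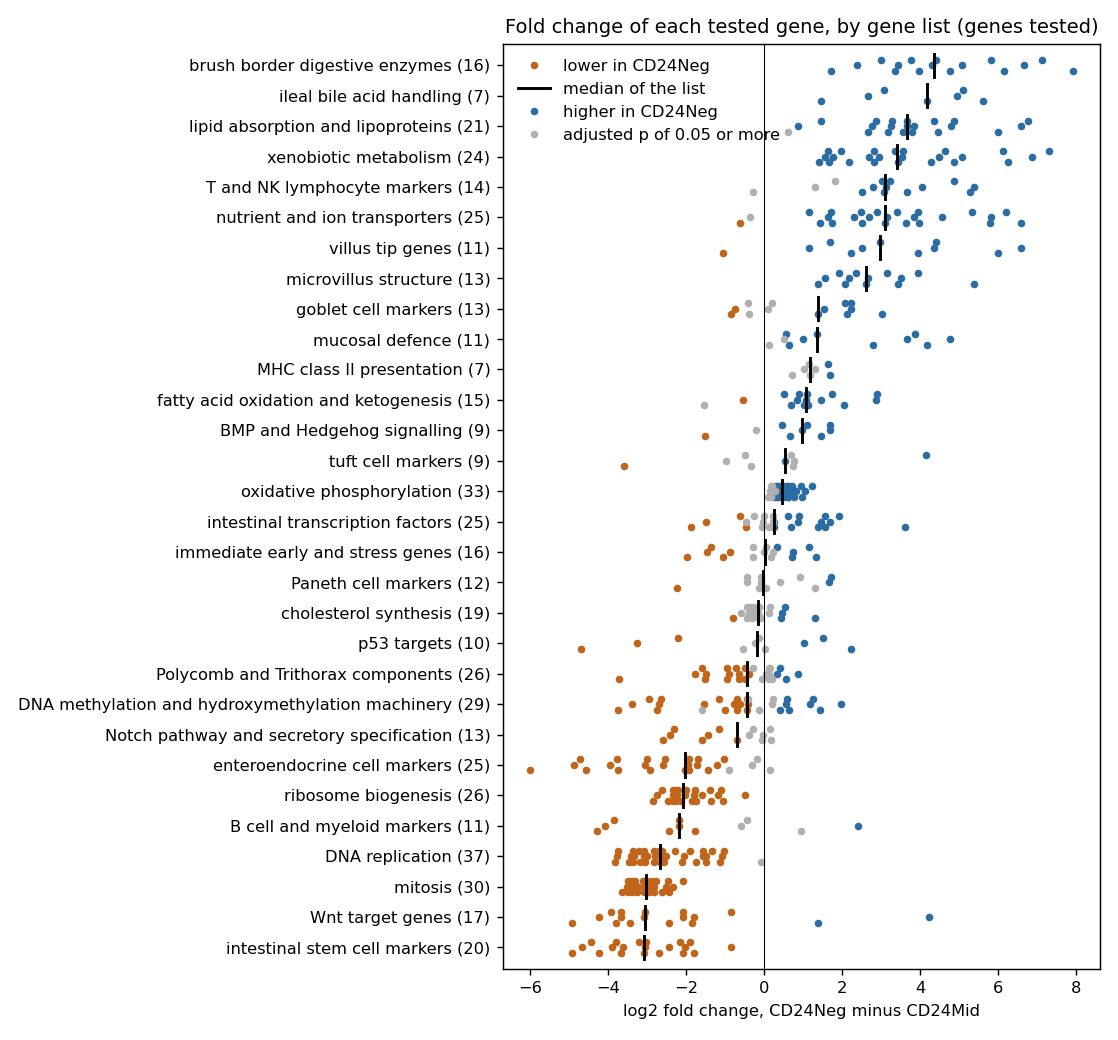
Log2 fold change (CD24Neg minus CD24Mid) of each tested member of the 30 gene lists with at least 5 tested genes, coloured by limma call, with the list median as a black bar and the number of genes tested in parentheses. Digestive enzymes (median 4.36) and ileal bile acid genes (4.17) stand at the top, and stem cell markers (-3.08) and Wnt targets (-3.06) at the bottom.

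The secretory lineages did not move together. Of 25 enteroendocrine markers 21 were lower in CD24Neg and none was higher (median log2 fold change -2.04, camera adjusted p = 3.71e-05, adjusted p = 0.345 with an estimated correlation). The granin genes Chga (1786 ± 505 against 300.0 ± 69.1) and Chgb (3180 ± 1117 against 380 ± 122) and Tac1 fell, and so did Neurog3, the transcription factor that commits cells to this lineage, at 138 ± 60.2 against 2.90 ± 3.79, the latter within a few reads of 0. The size of the Neurog3 difference rested partly on single libraries, with a log2 fold change of -6.01 in all libraries, -5.32 without CD24Neg library 2 and -6.72 without CD24Neg library 4. The hormone gene Cck did not differ detectably (274 ± 62.9 against 301 ± 71.6, adjusted p = 0.572). Of 13 goblet cell markers 7 were higher, 2 lower and 4 not called (median 1.39), and the list was not called (camera adjusted p = 0.115). The mucin gene Muc2 was 4.72-fold higher in CD24Neg (7208 ± 1417 against 37230 ± 19170), Zg16 8.14-fold and Clca1 4.68-fold. The transcription factor Creb3l1 was lower (580 ± 113 against 331 ± 121) and so was Galnt12, named after its values were seen (581 against 358). The Creb3l1 call ended without CD24Neg libraries 2 and 8 (adjusted p = 0.0555) and in the test against a fold change of 1.5 (0.287), within a range of 0.000291 to 0.287 over 22 alternatives. The goblet list passed under the scaling to totals without the 20 most abundant genes (adjusted p = 0.0418) and without CD24Neg library 6 (0.0442), within a range of 0.0418 to 0.238 over 21 alternatives.

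Camera called neither the Paneth nor the tuft cell list, while fry called the tuft list higher (fry adjusted p = 0.0473). Of 12 Paneth cell markers 2 were higher and 1 lower (adjusted over the list alone, 0 and 1), the median log2 fold change was -0.02, the mean 0.22 and the camera direction up (adjusted p = 0.896). Mmp7, the matrix metalloproteinase of Paneth granules, was 4.72-fold lower (233 ± 26.9 against 52.1 ± 20.97). The alpha-defensin genes Defa21 (41.4 ± 27.5 against 175 ± 192) and Defa22 (39.2 ± 23.5 against 163 ± 172) passed the threshold with all libraries. Without CD24Neg library 4 their log2 fold changes went from 1.71 and 1.68 to 1.06 and 1.05 (adjusted p = 0.0901 and 0.0768), and both calls also ended without CD24Mid library 1, 5 or 7 or CD24Neg library 8, within ranges of 0.00144 to 0.153 and 0.000961 to 0.146 over 22 alternatives. These genes belong to a family of near-identical copies, so the assignment of reads between them is uncertain. Of 9 tuft cell markers 2 were higher and 1 lower (adjusted over the list alone, 1 and 1), with a median of 0.53 (camera adjusted p = 0.788). With scaling to totals 1 was higher and 3 lower, and with quantile normalization 3 and 1, so the balance of this list depends on the scaling. Ltc4s, which encodes leukotriene C4 synthase, was higher (7.90 ± 4.80 against 135 ± 53.2), Plcg2 was slightly higher (269 ± 60.6 against 391 ± 96.0). Pou2f3, the tuft lineage transcription factor, was lower (26.6 ± 14.5 against 2.71 ± 3.38), with CD24Neg values within a few reads of 0. Its log2 fold change was -3.59 in all libraries, -2.90 without CD24Neg library 2 and -4.25 without CD24Neg library 4. The Plcg2 call ended when any 1 of CD24Mid libraries 1, 3 and 5 and CD24Neg libraries 2 and 8 was left out (adjusted p from 0.0664 to 0.119) and under the scaling to totals (0.7), within a range of 0.00178 to 0.978 over 22 alternatives. Of 13 Notch pathway and secretory specification genes 7 were lower and none higher (median -0.70, camera adjusted p = 0.0163, adjusted p = 0.238 with an estimated correlation). The receptor gene Notch1 was 6.07-fold, Notch2 5.00-fold and the target gene Hes1 2.73-fold lower. The ligand gene Dll1 was at 704 ± 82.1 against 801 ± 106 (adjusted p = 0.213).

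The enzymes that write, maintain and oxidise DNA methylation were considered next, since the series is about 5-hydroxymethylcytosine. Tet1, 1 of the 3 genes for the dioxygenases that oxidise 5-methylcytosine, was lower in CD24Neg (54.8 ± 20.6 against 5.22 ± 2.69, adjusted p = 0.000172), where its values lie within a few reads of 0, so no fold is given. Tet2 was 1.55-fold higher (342 ± 81.3 against 528 ± 93.7, adjusted p = 0.0139), and Tet3, the most abundant of the 3, did not pass the threshold (1531 ± 159 against 1797 ± 97.52, adjusted p = 0.0594). Blocked on adjacent title numbers, Tet3 passed (adjusted p = 0.0415, range 0.0415 to 1 over 22 alternatives). The Tet2 call ended under the scaling to totals (log2 fold change 0.21, adjusted p = 0.36) and with no filter on low values (adjusted p = 0.0516), within a range of 0.0015 to 0.709 over 22 alternatives. The maintenance methyltransferase gene Dnmt1 (3046 ± 281 against 403 ± 128) and its partner Uhrf1 (2129 ± 189 against 177 ± 91.0) were 7.81-fold and 13.4-fold lower. Among the de novo methyltransferases, Dnmt3a did not pass (values of 875 to 1109 against 812 to 972, adjusted p = 0.284) and neither did Dnmt3b (73.0 ± 31.3 against 29.0 ± 17.5, adjusted p = 0.0563). Dnmt3b passed without CD24Mid library 3 (adjusted p = 0.0391) or CD24Neg library 2 (0.0299) and under the scaling to totals (0.0239), within a range of 0.0204 to 0.195 over 22 alternatives.

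In the whole list of methylation and hydroxymethylation machinery, 8 of 29 tested genes were higher and 16 lower (adjusted over the list alone, 9 and 17), with a median log2 fold change of -0.45 (camera adjusted p = 0.0821). These counts were 4 and 20 with scaling to totals and 7 and 18 with quantile normalization. With quantile normalization this list was called lower (adjusted p = 0.0409, range 0.0409 to 0.133 over 21 alternatives). The chromatin remodeller Hells was 6.43-fold and the abasic site endonuclease Apex1 6.20-fold lower. Idh1, a cytosolic isocitrate dehydrogenase that makes 2-oxoglutarate, was 3.96-fold higher (1214 ± 202 against 4826 ± 831). Dnmt3a was called lower with quantile normalization (log2 fold change -0.39, adjusted p = 0.00538) and with the scaling to totals (-0.56, adjusted p = 0.00088), against a range of 0.00088 to 1 over 22 alternatives. Of 26 Polycomb and Trithorax components 14 were lower and 4 higher (median -0.44, camera adjusted p = 0.046, adjusted p = 0.348 with an estimated correlation), against 19 lower and 1 higher with scaling to totals and 15 lower and 3 higher with quantile normalization. Ezh2, the histone H3 lysine 27 methyltransferase, was 3.03-fold lower (1040 ± 157 against 342 ± 44.1) and its partners Rbbp7 and Rbbp4 were 3.405-fold and 2.81-fold lower. The demethylase gene Kdm6b was 1.84-fold higher (969 ± 98.7 against 1783 ± 149). Kmt2b and Cbx8, named after their values were seen, were also higher. The Polycomb list was not called without CD24Mid library 5 (adjusted p = 0.0559), CD24Neg library 2 (0.0852) or CD24Neg library 4 (0.0702), nor when genes with a log2 value above 0 in every library of 1 group were tested (0.0513), within a range of 0.0156 to 0.094 over 21 alternatives.

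**Figure D3:**
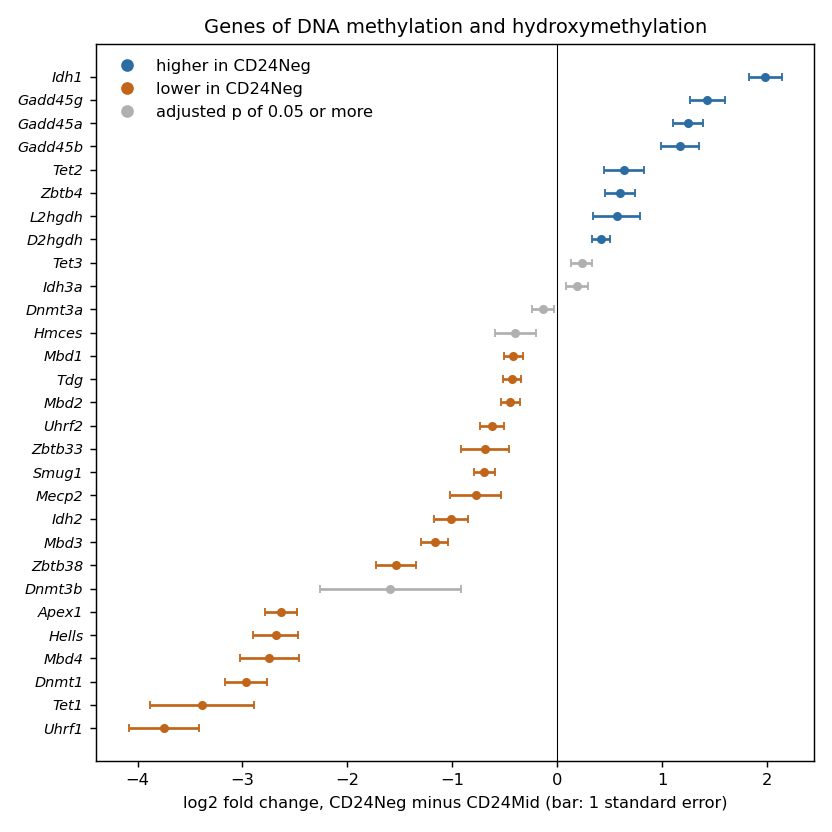
Log2 fold change (CD24Neg minus CD24Mid, bar of 1 standard error) of 29 genes of DNA methylation and hydroxymethylation, coloured by limma call. Uhrf1 (-3.75), Tet1 (-3.39) and Dnmt1 (-2.97) are the lowest and Idh1 (1.99) is the highest. The size and rank of the Tet1 change are uncertain, since its CD24Neg values (1.413 to 7.545) amount to only a few reads. Dnmt3a, Dnmt3b and Tet3 are among the 5 genes that did not pass.

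Transcription factors of the intestinal epithelium went both ways. Of 25 tested, 13 were higher and 4 lower in CD24Neg (median log2 fold change 0.25, camera adjusted p = 0.083). Maf rose 12.4-fold (497 ± 170 against 5888 ± 792), Klf4 3.24-fold, Gata5 2.60-fold and Esrra, an orphan nuclear receptor, 2.97-fold. Foxa1 was 2.83-fold lower (371 ± 59.3 against 133 ± 31.8), and the other lower members, named after their values were seen, were Foxa2, Cdx1 and Hnf4a. The list was called higher without CD24Neg library 8 (adjusted p = 0.0438) and with no filter on low values (0.0144), within a range of 0.0144 to 0.558 over 21 alternatives. Under the scaling to totals 9 were higher and 10 lower and the median was -0.18, where the median of all genes was -0.45. With quantile normalization 11 were higher and 9 lower. Of 9 BMP and Hedgehog signalling genes 7 were higher and 1 was lower (median 0.96, camera adjusted p = 0.0367, adjusted p = 0.348 with an estimated correlation). The ligand genes Ihh (548 ± 113 against 1739 ± 148) and Bmp2 (69.8 ± 13.1 against 227 ± 35.1) were each over 3-fold higher, and the Hedgehog receptor gene Ptch1 was 2.88-fold lower. With quantile normalization this list was not called (adjusted p = 0.0609, range 0.00633 to 0.0609 over 21 alternatives).

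Mitochondrially encoded transcripts took a larger share of the CD24Neg libraries. The 17 mitochondrially encoded genes held 8.58% ± 0.518 of all values in CD24Mid and 32.6% ± 4.63 in CD24Neg, a 3.79-fold difference (exact two-sided permutation p = 0.0286, the smallest p that 4 libraries against 4 allow). The share was 35.6%, 28.3%, 28.9% and 37.4% in CD24Neg libraries 2, 4, 6 and 8. Of 33 nuclear genes of oxidative phosphorylation 26 were higher in CD24Neg and none was lower (adjusted over the list alone, 27 and 0), but by less: the median log2 fold change was 0.46 (camera adjusted p = 0.000103, adjusted p = 0.556 with an estimated correlation). Ndufa1 was 2.36-fold (612 ± 131 against 1427 ± 142) and Uqcrfs1 1.92-fold higher. With quantile normalization this list had a median of -0.01 and was not called (adjusted p = 0.79, range 9.4e-08 to 0.79 over 21 alternatives), and under the scaling to totals its median was 0.03 where that of all genes was -0.45. The counts of higher and lower genes were 6 and 5 with quantile normalization and 7 and 2 under the scaling to totals.

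Of 15 genes of fatty acid oxidation and ketogenesis 13 were higher and 1 was lower (median log2 fold change 1.07, camera adjusted p = 0.00691, adjusted p = 0.556 with an estimated correlation). Under the scaling to totals 9 were higher and 1 was lower, and with quantile normalization 8 were higher and 1 was lower. Ehhadh, a peroxisomal enzyme gene of this pathway, was 3.37-fold and Cpt2 2.05-fold higher. Cpt1a, which encodes the mitochondrial carnitine palmitoyltransferase of the outer membrane, was 1.46-fold lower (4855 ± 1282 against 3284 ± 563, adjusted p = 0.0304). The Cpt1a call ended without CD24Mid library 1 (adjusted p = 0.0723) or 5 (0.077) or CD24Neg library 6 (0.0697) or 8 (0.089), within a range of 0.000571 to 0.955 over 22 alternatives. Of 19 genes of cholesterol synthesis 4 were higher, 1 was lower and 14 were not called (median -0.15, camera adjusted p = 0.896). Under the scaling to totals 1 was higher and 9 were lower, and with quantile normalization 1 was higher and 5 were lower. Sc5d was 2.46-fold higher and Idi1 was 1.73-fold lower.

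**Figure D4:**
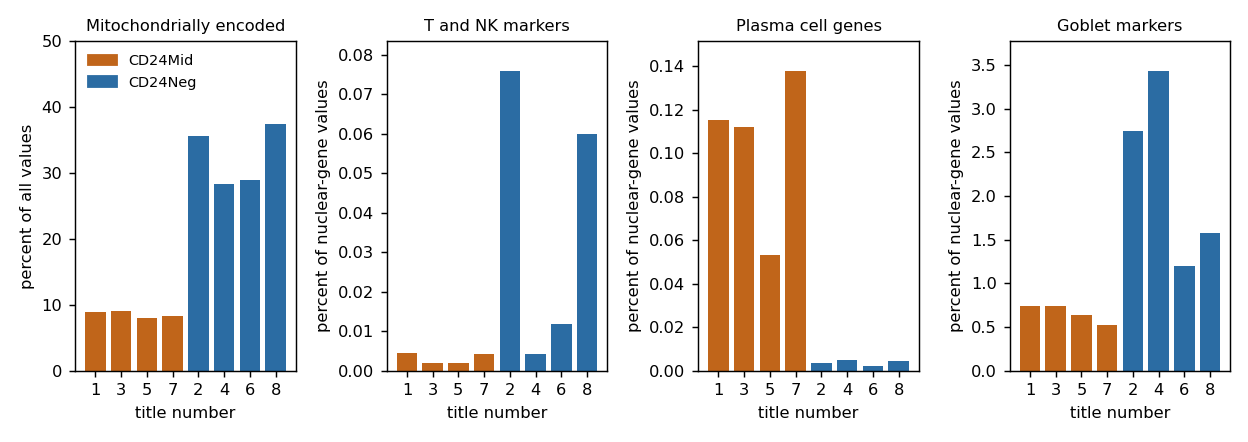
Shares per library, by title number: mitochondrially encoded genes as a percent of all values, and T and NK lymphocyte markers, 3 plasma cell genes (Jchain, Igkc and Mzb1) and goblet cell markers as percents of the values of nuclear genes. Bars start at 0. CD24Neg libraries 2 and 8 hold the largest lymphocyte shares (0.0758% and 0.0600%), and the CD24Mid libraries hold 0.0532% to 0.138% plasma cell transcripts.

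Markers of leukocytes, which the CD45 depletion was meant to remove, were present in both fractions at low shares. Of 14 T and NK lymphocyte markers 11 were higher in CD24Neg (median log2 fold change 3.12, camera adjusted p = 0.00994, adjusted p = 0.56 with an estimated correlation). Gzma, a granzyme gene, had 31.6 ± 20.7 in CD24Mid and values of 3889, 212, 549 and 2742 in CD24Neg libraries 2, 4, 6 and 8, and Gzmb, Ccl5 and Cd8a were also highest in libraries 2 and 8. Without CD24Neg library 4 the log2 fold changes of Gzma, Gzmb, Ccl5 and Cd8a were 6.05, 6.23, 5.76 and 4.35 in place of 5.28, 5.39, 4.87 and 3.67. Without library 2 those of Gzma, Gzmb and Ccl5 were 4.66, 4.80 and 4.21. The summed T and NK markers were 0.0758%, 0.0042%, 0.0118% and 0.0600% of nuclear-gene values in these libraries and 0.0031% ± 0.0014 in CD24Mid, a difference that did not pass an exact two-sided permutation test of unpaired libraries (p = 0.0571). In each of the 4 pairs of adjacent title numbers, which the labels do not call pairs, the CD24Neg library had the higher share. Without CD24Neg libraries 2 and 8, a choice made after the data were seen, the list was not called (adjusted p = 0.06, range 0.000141 to 0.06 over 21 alternatives) and 4355 genes were higher and 4346 lower in CD24Neg.

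Of 11 B cell and myeloid markers 7 were lower and 1 was higher in CD24Neg (median log2 fold change -2.17, camera adjusted p = 0.0367, adjusted p = 0.534 with an estimated correlation). The lower members with the smallest adjusted p included 3 genes of antibody-secreting and B cells, Jchain (5512 ± 1915 against 280 ± 98.6), Mzb1 (66.6 ± 21.5 against 3.75 ± 2.48) and Cd79a (51.0 ± 11.4 against 3.64 ± 2.92), and Cd14, a myeloid receptor gene. The Fc receptor subunit Fcer1g was higher (11.3 ± 6.71 against 74.4 ± 59.7), a call that ended without CD24Neg libraries 2 and 8 (adjusted p = 0.084, range 0.00022 to 0.084 over 22 alternatives). This list was not called without CD24Mid library 1 (adjusted p = 0.0568) or CD24Neg library 4 (0.0531), with quantile normalization (0.0806) or under the scaling to totals (0.156), within a range of 0.00553 to 0.156 over 21 alternatives. Of 16 stromal and endothelial markers 3 reached the minimum value, and of these Vim was lower (144 ± 26.3 against 63.7 ± 45.9, adjusted p = 0.0158). The Vim call ended with no filter on low values (adjusted p = 0.0664) and in the test against a fold change of 1.5 (0.107), within a range of 5.92e-05 to 0.107 over 22 alternatives. Pecam1 and Pdgfrb were not called. Of the 8 erythroid markers 5 were among the deposited genes, and none reached the minimum value. Of 7 genes of MHC class II presentation 2 were higher (adjusted over the list alone, 0), H2-Ab1 (1135 ± 783 against 3299 ± 1731, adjusted p = 0.0136) and H2-Aa (582 ± 443 against 1663 ± 1164, adjusted p = 0.0266), with a median of 1.18 (camera adjusted p = 0.142). The H2-Aa call ended without any 1 of CD24Mid libraries 3 and 5 and CD24Neg libraries 2 and 8, with adjusted p from 0.0547 to 0.072, and with quantile normalization (0.0508), no filter on low values (0.106) or scaling to totals (0.0856), within a range of 0.000549 to 0.153 over 22 alternatives. The H2-Ab1 call ended without CD24Neg libraries 2 and 8 together (0.0907) and with no filter on low values (0.0679), within a range of 0.000634 to 0.0907. Neither gene passed the test against a fold change of 1.5 (0.118 for H2-Aa, 0.0727 for H2-Ab1). The list passed without CD24Mid library 7 (adjusted p = 0.0436) and blocked on adjacent title numbers (0.00876, range 0.00876 to 0.31 over 21 alternatives).

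Of 11 mucosal defence genes 9 were higher in CD24Neg (median log2 fold change 1.35, camera adjusted p = 0.00202, adjusted p = 0.345 with an estimated correlation). The secreted lectin genes Reg3a (158 ± 75.2 against 4202 ± 1187) and Reg1 (1355 ± 838 against 18620 ± 5738) were 27.5-fold and 14.8-fold higher, the cytokine gene Il18 12.7-fold and the chemokine gene Ccl25 2.54-fold. The members that did not pass, named after their values were seen, were Duox2 and Duoxa2. Under the scaling to totals 7 members were higher and 0 lower, and with quantile normalization 6 were higher and 1 lower. The list was called higher in all 21 alternatives (camera adjusted p from 0.000167 to 0.0394). The CD24Neg fraction also held the lymphocyte transcripts described above, mainly in libraries 2 and 8. In CD24Neg library 4, with a T and NK share of 0.0042%, Reg3a (5271) and Reg1 (24190) were highest. Il18 (893) and Ccl25 (8607) were at their CD24Neg lowest in that library.

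Stress and p53 response genes gave no list call. Among 16 immediate early and stress genes 5 were higher and 5 lower (median log2 fold change 0.02, mean -0.16, camera direction down with adjusted p = 0.962), with Junb (2856 ± 867 against 6226 ± 1179) and Ier3 higher and Fosb (5100 ± 1820 against 2405 ± 594) and Nr4a1 lower. Under the scaling to totals 2 were higher and 7 lower (median -0.41), and with quantile normalization 2 were higher and 9 lower (median -0.54). Of 10 p53 targets 3 were higher and 3 lower (median -0.19, camera adjusted p = 0.896), and under the scaling to totals 3 were higher and 7 lower. Cdkn1a (571 ± 92.1 against 2680 ± 198), Bbc3 and Mdm2 were higher, Aen was 4.62-fold lower, and so were Eda2r and Phlda3, named after their values were seen.

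Across single genes, the largest positive changes among well-expressed genes without overlap of the fractions were in Sco2, Slc5a12, Tmprss15, Plb1, Pdzk1 and Gdpd2. Pdzk1, a scaffold of brush border transporters, was at 27.3 ± 8.57 in CD24Mid and 4984 ± 1961 in CD24Neg (log2 fold change 7.45, SE 0.30, adjusted p = 1.75e-07), the phospholipase gene Plb1 at 13.6 ± 6.43 against 3334 ± 1220 (238-fold) and Gdpd2 at 14.6 ± 4.30 against 2376 ± 653 (159-fold). Slc5a12, a lactate transporter, had values of 0 to 1.32 in CD24Mid and 340 to 1749 in CD24Neg, and Tmprss15, which encodes enteropeptidase, had 0 to 3.17 against 240 to 467. No fold is given for either because the CD24Mid values lie within a few reads of 0. Sco2, a copper chaperone gene, was listed at about 0 in each CD24Mid library and at 571, 663, 761 and 904 in the CD24Neg libraries. Its value is uncertain, because 68.3% of its annotated exonic bases are shared with Tymp, which had 69.1 ± 18.0 in CD24Mid and 748 ± 91.5 in CD24Neg.

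The largest negative changes by the same rule were in Tmem254a, Timeless, Ascl2, Gip, Msi1 and Sfrp5. Ascl2, a Wnt-responsive transcription factor of stem cells, was lower in CD24Neg (269 ± 66.1 against 9.41 ± 5.64, adjusted p = 4.61e-06), the RNA-binding protein gene Msi1 25.5-fold lower (421 ± 68.4 against 19.6 ± 13.4) and the Wnt antagonist gene Sfrp5 24.8-fold lower (459 ± 143 against 18.9 ± 8.88). Timeless, a component of the replication fork, had 507 ± 34.2 in CD24Mid and values of 4.57, 8.97, 6.83 and 56.1 in CD24Neg, with a log2 fold change of -5.41 in all libraries and -6.16 without CD24Neg library 8. Gip, an enteroendocrine hormone gene, spread widely in CD24Mid, from 420 to 5871, and its log2 fold change of -4.72 became -4.00 without CD24Mid library 3, -4.08 without CD24Neg library 2 and -5.44 without CD24Neg library 4. Tmem254a (253 ± 19.0 against 21.7 ± 37.4) belongs to a group of near-identical copies, so its value is uncertain, and its log2 fold change of -5.49 became -4.73, -6.75 and -4.77 without CD24Neg libraries 2, 4 and 8. The sizes of the Ascl2, Timeless and Tmem254a changes are uncertain, since some CD24Neg values of each lie within a few reads of 0.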

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

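Among the tests in this part, those of the mitochondrial share against abundant nuclear genes and against a rise in both genomes, and the test of the goblet pattern against a lower share of the main cell type, were chosen after the result was seen. In 24 of 320 groups of 4 libraries, 1 library lay far from the other 3 by Dixon's test, where chance gives about 1 in 20 groups, or 16.0. Many of these genes vary together over the same libraries, and the values were tested without logs. The excess over 16.0 was therefore not tested, and the values listed for a library need not be separate events. In CD24Mid library 1 the values that stood apart were Abcg5 1393 (others 813.7 to 892.7), Ehhadh 1047 (830.1 to 850.2), Esrra 2433 (1735 to 1808), Idh1 1516 (1081 to 1131), Reg1 2606 (836.8 to 1031), Reg3a 270.1 (115.9 to 127.3) and Slc51a 1146 (525.3 to 579.4). In CD24Mid library 3 they were Aurka 874.8 (787.4 to 797.5), Creb3l1 748.3 (507.9 to 535.6), Gip 5871 (419.6 to 1341), Plb1 23.1 (8.857 to 11.29), Rbbp4 3466 (2465 to 2512) and Uhrf1 2410 (1996 to 2060) above the others, and Kdm6b 822 (998.2 to 1028) and Slc36a1 294.9 (320.5 to 323.4) below them. In CD24Mid library 5 they were Fut2 13.14 (6.893 to 7.432) and Tmem254a 224.6 (261.1 to 264.2). In the CD24Neg libraries they were Klf4 1905 (2895 to 3041) and Nr4a1 162.3 (81.84 to 91.43) in library 2, Defa5 114.6 (17.71 to 32.63), Slc51b 838.4 (1136 to 1154) and Tmem254a 77.57 (0.7007 to 7.851) in library 4, and H2-Aa 3392 (893.1 to 1287) and Timeless 56.13 (4.568 to 8.968) in library 8.

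The split of the libraries by fraction was compared with the other splits of the 8 libraries into 4 and 4. For genes higher in CD24Neg, 1 of 35 splits, the real one, gave as many calls (4386, highest other 0), and for genes lower 1 of 35 (4423, highest other 0). This is the smallest share that 35 splits allow. The other splits mix the fractions and so put a difference between them into the spread within each side. A count of 0 was therefore likely there, and the comparison alone does not exclude chance. At an unadjusted p under 0.05 the other splits gave at most 686 genes in a direction, against 4570 and 4611. For the list counts, over all 35 splits, chance cannot be excluded: 11 of 35 splits called as many lists as the 12 higher ones (highest other 14) and 17 of 35 as many as the 9 lower ones (highest other 14). All other splits that reached these counts put 3 libraries of a fraction with 1 of the other and so keep part of the difference between the fractions. The 18 splits with 2 libraries of each fraction on each side called at most 8 lists in a direction.

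Mitochondrially encoded transcripts held 3.79 times the share in CD24Neg that they held in CD24Mid. Without the 20 most abundant nuclear genes in the total the ratio was 3.89, and the lowest ratio of any CD24Neg to any CD24Mid library was 3.23. This could hardly come out otherwise. The 20 most abundant genes of the CD24Mid libraries, mitochondrial ones included, held 13.3% ± 0.393 of the values. That small share itself leaves little room for a few abundant nuclear genes as the cause. The size factor of a library cancels in the mitochondrial share. The median log2 fold change of 15 mitochondrially encoded genes exceeded that of 33 nuclear oxidative phosphorylation genes by 2.29 (2.75 against 0.46, bootstrap interval over genes 2.06 to 2.53), which argues against a rise of both genomes by the same factor. The interval resamples genes that vary together (estimated correlation 0.818 in the nuclear list), so it does not measure the spread between libraries. With quantile normalization the gap was 0.90, inside the bound of 1 for such a rise, but 9 of the 15 genes were among the 20 most abundant of every library, where this normalization limits how far genes can differ. For the other 6 genes it was 2.27 (log2 fold changes 1.64 to 3.38). These include the largest changes of the 15 genes in the main fit, mt-Nd4l (4.04), mt-Rnr1 (3.855) and mt-Rnr2 (3.591), so they need not stand for all 15. The remaining members, mt-Atp8, mt-Nd6 and mt-Nd3, had 1.64, 1.70 and 2.15 with quantile normalization. Damage or RNA loss of sorted CD24Neg cells stays open, because no RNA quality value per library is at hand and the stress list, with a median of 0.022, decides nothing. A difference in mitochondrial transcripts between the cells of the fractions also stays open and was not tested.

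Leukocyte transcripts appeared in both CD45-depleted fractions, of T and NK cells mainly in CD24Neg libraries 2 and 8 and of plasma cells in CD24Mid. Over the 4 CD24Neg libraries, 15 T and NK genes held out of the list had a median correlation of 0.99 with the list's mean, above 100% of 10000 random sets matched on expression (random median 0.03), which is consistent with lymphocytes passing the depletion, over 4 libraries only. The random genes, here and in the tests below, were drawn singly, so the sets lack the co-variation of any co-regulated group. The percentile therefore does not separate lymphocytes from another difference that follows libraries 2 and 8. The mitochondrial share was also higher there (35.6% and 37.4%) than in libraries 4 and 6 (28.3% and 28.9%). The median log2 fold change of these 15 held-out genes was 1.13, against 3.12 for the list. Several of them were not called, among them Coro1a (0.45) and Cd53 (-0.16). The list shares 0 genes with the other lists, and 7 of its genes were at 10 or more in all CD24Mid libraries and 11 in all CD24Neg libraries, with Gzma up to 3889. For plasma and B cells, 10 held-out genes had a median log2 fold change of -1.55, which met the bound set for such cells passing into CD24Mid but lay at the 7.9 percentile of random sets. Of the held-out plasma and B cell genes, 9 were at 10 or more in all CD24Mid libraries and 2 in all CD24Neg libraries. Most could thus pass the filter on low values through CD24Mid alone, which favours a negative median. Meeting the bound therefore does not decide the question. The most abundant plasma cell genes were Igkc (5649 ± 1988 against 277 ± 92.5, chosen after its values were seen) and Jchain (5512 ± 1915 against 280 ± 98.6), and expression of these genes by the sorted epithelial cells was not tested.

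Goblet cell markers made up 0.662% ± 0.106 of nuclear-gene values in CD24Mid and 2.24% ± 1.03 in CD24Neg (exact two-sided permutation p = 0.0286, the smallest that the design allows), although the Ulex lectin depletion was meant to lower such cells. Enteroendocrine markers had a median log2 fold change of -2.04 (bootstrap interval over markers, not libraries, -3.05 to -1.69). Paneth markers had -0.02 against 1.39 for goblet markers, so the markers of these types did not move alike. The sort on CD24 can itself take cell types unevenly. The comparison therefore cannot decide whether a lower share of the main cell type raised the goblet markers. Goblet cells passing the depletion into CD24Neg stay open: 14 held-out goblet genes had a median of 0.39, at the 94.8 percentile of 10000 random sets, between the bounds set beforehand. The most abundant markers of the list were Fcgbp (32510 ± 4450 against 149500 ± 74110, chosen after its values were seen) and Zg16 (8905 ± 3755 against 72750 ± 34070). The fractions' shares of Paneth markers (0.0254% against 0.0216%, exact permutation p = 0.5429) and of enteroendocrine markers (0.0948% against 0.0136%, exact permutation p = 0.0286) are given for comparison.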

How the results depend on the processing

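Chosen after the data were seen were the voom weights, the fit without CD24Neg libraries 2 and 8, the block on adjacent title numbers and the fit without mitochondrially encoded genes. Cd24a was lower in all 22 alternatives run (log2 fold change -2.62 to -3.22). Scaling to totals without the 20 most abundant genes gave 2831 genes higher and 6534 lower, with 2830 and 4420 of the original calls kept and 5 called in the opposite direction. This scaling moved the median of all genes to -0.45. Quantile normalization gave 4052 higher and 4593 lower, with 3696 and 4000 of the original calls kept and 8 called in the opposite direction. The test against a fold change of 1.5 gave 2360 higher and 2430 lower by construction and no list result. Camera with an estimated correlation called 0 lists higher and 0 lower, with 1 list at an unadjusted p under 0.05, where fry called 15 and 10. Leaving out 1 library gave 4168 to 4428 genes higher, 4160 to 4440 lower, 12 to 13 lists higher, 7 to 9 lower and a Cd24a change of -2.62 to -2.95. The voom fit gave 4438 and 4419 genes, the fit without CD24Neg libraries 2 and 8 gave 4355 and 4346, and that without mitochondrially encoded genes 4379 and 4413. Over 148 other named genes and 3256 combinations with alternatives, 63 calls ended, 30 appeared and 0 turned, in 25 genes. Some of these calls ended in the test against a fold change of 1.5, which can only end calls. Those of Fosb, Idi1, Ndufb3 and Slc16a1 ended only there. The cause of the changes in the other alternatives was not tested. The labels pair no libraries across the fractions, which share no title numbers. A block on adjacent numbers, as a hint from the data only, gave 4732 and 4771 genes and calls for Ptprc (adjusted p = 0.006), Tet3 (0.0415), Defa5 (0.0037), H2-DMb1 (0.00112), H2-Eb1 (0.00231), Il17rb (0.0467) and the MHC class II list (0.00876). The alternative on a different unit was not run, because there is 1 value per gene. Depth limits low genes most in CD24Neg, where 1 read is worth up to 1.79.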

Other observations

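The gene families in this part were chosen by symbol pattern after the data were seen, as was the test of adjacent title numbers. Camera called 17 of 20 such families, of which 8 are described, and did not call proteasome subunits (adjusted p = 0.227), annexins (0.104) or claudins (0.522). Cytosolic ribosomal protein genes were lower in CD24Neg in 78 of 81 cases and higher in 1 (median log2 fold change -1.11, camera adjusted p = 2.32e-12, adjusted p = 0.375 with an estimated correlation), with Rpl3 at 19988 ± 3296 against 6997 ± 1556. Of 19 nucleoporin genes 18 were lower (median -1.35, camera adjusted p = 1.03e-06, adjusted p = 0.346 with an estimated correlation), with Nup93 at 737 ± 59.0 against 203 ± 46.6. Of 39 splicing factor genes 32 were lower and 2 higher (median -0.86, camera adjusted p = 1.38e-07, adjusted p = 0.246 with an estimated correlation), and all 8 cytosolic chaperonin subunits were lower (median -1.04, camera adjusted p = 0.000223, adjusted p = 0.346 with an estimated correlation). These 4 families had medians below 0 with quantile normalization and with scaling to totals as well.

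Of 36 cytochrome P450 genes, some of which are in the xenobiotic list, 29 were higher in CD24Neg and 4 lower (median log2 fold change 3.36, camera adjusted p = 1.53e-06, adjusted p = 0.346 with an estimated correlation). Of 19 MHC class I genes 13 were higher and 1 lower (median 1.31, camera adjusted p = 0.000308, adjusted p = 0.351 with an estimated correlation), with H2-K1 at 4675 ± 1013 against 20248 ± 2478, and these genes have near-identical copies, so their values are uncertain. Of 251 solute carriers 135 were higher and 53 lower (median 0.61, camera adjusted p = 4.38e-05, adjusted p = 0.346 with an estimated correlation). The medians of these 3 families stayed above 0 under both other scalings, at 0.18 for solute carriers with scaling to totals. The median of the 15 tested mitochondrially encoded genes, 2.75, was 2.33 with scaling to totals and 0.88 with quantile normalization.

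Libraries with adjacent title numbers may share an animal or a day: of the 24 ways to pair CD24Mid with CD24Neg libraries, 1, that of adjacent numbers, reached the highest sum of correlations of the deviations from the group means (1.37, highest other 0.85, exact permutation p = 0.0417, over 10754 genes), a hypothesis found and tested on the same data.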
